A study of Mus musculus with 72 samples.

How the data were processed

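The series measured the output of barcoded mPGK reporters in EBRTcH3 mouse embryonic stem cells, in 6 pools (mPGK-A to mPGK-F). Per the labels' protocols, cells with low eGFP were grown for 5 days after sorting, small pools were grown for 7 days, and each was then split into 2 cultures grown for 7 more days, which serve as technical replicates. For each culture, barcodes were amplified and sequenced from reverse-transcribed RNA (expression) and from genomic DNA (normalization), and integration sites were mapped by inverse PCR after digestion with DpnII, each in 2 PCRs. This gives 72 libraries in 18 groups of 4, with 12 libraries per pool.

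The deposited table lists 17857 integrations with pool, barcode, chromosome, position, strand and raw counts of DNA and RNA reads per replicate. Per the submitters' processing notes, Bowtie2 2.0 and mm9 were used. How the authors combined the counts of the 2 PCRs, which barcodes they kept, and whether positions are counted from 0 or 1 is not given in the sources used here, so a position may be off by a single base. Coordinates are those of mm9 as listed, with window bounds counted from 1. Totals are sums over the listed barcodes, not the depth of whole libraries, so ratios are relative to the listed barcodes of a pool. The mapping libraries enter only through the listed positions.

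Expression was the log2 ratio of the RNA share to the DNA share of a barcode in a pool and replicate, with a pseudocount of 0.5 RNA reads (0.5 times the lowest count above 0), averaged over the replicates. For all results of expression but the comparison of pools, the pool median was subtracted. The pseudocount sets the value of integrations with few RNA reads, so single integrations without RNA reads are given as counts and as a bound from a floor of 3 reads, while means of chromosomes and windows include them at the value the pseudocount gives. Differences between chromosomes, windows and strands were tested by permuting values between integrations of the same pool (100000 resamples, two-sided). Pairs of integrations were compared in 10 distance classes with the correlation over pairs, permuting within pool and chromosome (one-sided), with a jackknife over chromosomes for the SE. Windows were fixed stretches of 2 Mb with at least 5 integrations. Local density was the number of other integrations of any pool within 100 kb, tested with the GC content of barcodes in a family of 4 relations. Pool medians have intervals from 2000 bootstrap resamples. Adjusted p-values follow Benjamini and Hochberg with a threshold of 0.05. Integrations, not cultures or animals, are the units of these tests.

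RNA and DNA counts of each barcode were compared within a pool with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, filterByExpr, which removed no barcode, and TMM scaling, then shifted so that the median ratio of the pool is 0), with DESeq2 1.42.0 as an alternative. The shift moved the medians by 0.22 to 0.28 log2 units, since at TMM scaling they lay between -0.28 and -0.22. Replicate numbers pair RNA and DNA from the same culture, per the labels. The RNA and DNA deviations of the replicates had correlations of -0.00212 to 0.0576 across barcodes in the pools. All other values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0.

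The tests were tested on simulated data. With values placed at random over the 17857 real positions, 0 of 21 chromosomes, 0 of 1116 windows and 0 of 10 distance classes passed in 20000 resamples. With 100 windows moved by 2 log2 units, 47 were called with the right sign, so smaller or thinly filled regions can be missed. In the same simulation, with likeness in blocks of 50 kb, shuffling called 6 of 963 windows that had not been moved, and rotation called 0 of these and 0 of the 100 moved windows. For RNA against DNA in mPGK-A (2725 barcodes), 55.2% of barcodes changed 2-fold, 98.5% of those changed 4-fold and 100% of those changed 8-fold were called, and 0.277% of unchanged barcodes. These counts were simulated with the same dispersion, 0.054, for RNA and DNA of all barcodes. The data held larger errors at low RNA counts, so the rates may not carry over to the calls in the data.

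The tests, the alternatives and the rule for named regions were chosen before the data were examined, the named items being every chromosome past the threshold, the 10 highest and 10 lowest windows past it, and the 5 highest and 5 lowest integrations. The plan left the unit of the values open and gave the test of RNA against DNA counts for raw counts only, and the deposited values are raw counts per replicate. Alternatives were a 10 times larger pseudocount, leaving out the lowest 10% of DNA counts, leaving out each replicate or pool, ranks, no centring, barcodes of several pools used once, other windows, distances, pairs and permutations, and other count models. Rotation of values along the genome, comparison of chromosomes within classes of local density, a minimum of 10 RNA reads, TMM scaling without the shift and dropping single count columns were chosen after seeing the data. Planned comparisons with gene positions, gene lists and chromatin features were not run, because the gene annotation at hand is of another build than mm9 and chromatin features were not used here.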

Results

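Reporter expression was measured at 17857 genomic integration sites in mouse embryonic stem cells by TRIP, an assay in which many reporter genes, each carrying its own random DNA barcode, are inserted into the genome and read out in parallel. The cells were of the EBRTcH3 line, which expresses a tetracycline-controlled transactivator from the Rosa26 locus. Every reporter was driven by the same promoter, that of the mouse housekeeping gene for phosphoglycerate kinase (mPGK), and was delivered by the piggyBac transposon, which inserts at TTAA sites. The question asked by the design was how the place of integration changes the output of an identical reporter. The 6 cell pools, mPGK-A to mPGK-F, came from cells sorted for low eGFP signal. They held 2518 integrations (mPGK-C) to 3176 integrations (mPGK-B), with a mean of 2976 ± 283 (SD, n = 6 pools). Each pool had been split into 2 cultures grown apart, which served as technical replicates, and for each culture barcodes were counted in RNA and in genomic DNA. Over the listed barcodes, DNA counts summed to between 3386477 and 3693449 reads per pool and replicate, and RNA counts to between 2880244 and 3508366 reads. The median integration had 1670 DNA reads and 553 RNA reads over both replicates, and the lowest DNA count in a replicate was 18 reads. Expression is given as the log2 ratio of RNA to DNA share, averaged over both replicates and set relative to the median of its pool.

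Identical reporters differed widely in output between integrations. From the 5th to the 95th percentile of integrations, expression ran from -4.42 to 3.41 on the log2 scale around the pool median, a 229-fold range (7.84 log2 units, and 7.10 with a 10 times larger pseudocount), and the middle 50% of integrations spanned 8.29-fold. Of the 17857 integrations, 1157 (6.48%) lay more than 16-fold below the median of their pool and 441 (2.47%) more than 16-fold above it. No RNA read was counted in either replicate at 184 integrations (1.03%). The spread between integrations was far larger than the spread between replicates: the SD between integrations was 2.43 on the log2 scale, and the error SD of a replicate, from the differences between the replicates, was 0.78. The replicates ranked the integrations of a pool with a median Spearman rho of 0.940 over the 6 pools, from 0.932 in mPGK-B to 0.949 in mPGK-F. These correlations run across integrations, and the replicates were split from a shared pool late in culture, so this error covers the spread between technical replicates, not that between pools. Precision followed depth: in mPGK-A the error SD was 0.41 for the 68.3% of integrations with at least 100 RNA reads in each replicate, and 1.15 for the rest.

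Most single integrations departed from the median RNA to DNA ratio of their pool. In a test of RNA against DNA counts within each pool (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2 RNA and 2 DNA counts per barcode), 6585 integrations (36.9%) were higher than the median ratio of their pool and 6040 (33.8%) were lower at an adjusted p of 0.05. At TMM scaling without the shift to the pool median, the same test gave 5863 higher and 6835 lower, so which direction held more calls depended on the scaling. Each pool held calls in both directions, from 926 higher and 867 lower in mPGK-C to 1180 higher and 1085 lower in mPGK-F. The smallest differences called were 0.37 higher in mPGK-F and -0.41 in mPGK-A, on the log2 scale. The replicates are technical, so these p-values measure only the spread between cultures split from the same pool.

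The highest single integrations lay on chromosomes 11, 4 and 1. The strongest, barcode ATTTGAGAGCGAGATC of mPGK-A at position 8522893 on the plus strand of chromosome 11, was 159-fold above its pool median, with 7.34 and 7.28 on the log2 scale in the replicates and 19452 RNA reads against 155 and 205 DNA reads. The next, barcode ATGCCATGAATCTGA of mPGK-E at 69494934 on chromosome 11, was 146-fold above its pool median. Barcode ATATCGTAAATAGCCC of mPGK-D at 140853193 and barcode TTTGTCCGTTGCTGTA of mPGK-E at 140857158, both on the plus strand of chromosome 4 and from different pools, were 6.85 and 6.67 above their pool medians on the log2 scale. The fifth, barcode CCCGCCAACTTAAGTC of mPGK-F at 88399328 on chromosome 1, was 95.9-fold above. The replicates of the chromosome 4 pair were further apart, with 7.26 and 6.44 in mPGK-D and 5.97 and 7.36 in mPGK-E. DNA reads were few, with 221 and 80 for the latter and 143 and 83 for the mPGK-E integration on chromosome 11. The median over all integrations was 1670 over both replicates. The 5 lowest integrations by this measure were among the 184 with 0 RNA reads in both replicates, whose order is set by DNA depth, the scaling of the pool and the pseudocount. They are those of the 184 with the most DNA reads, and were not shown to be lower than the others without RNA reads. They had at least 7158 DNA reads in each replicate, and all lay on the minus strand. They were at 48974348 on chromosome 9 (mPGK-A, 8755 and 9825 DNA reads), 75591906 on chromosome 1 (mPGK-D), 45213782 on chromosome 16 (mPGK-A), 156961124 on chromosome 3 (mPGK-D) and 39911509 on chromosome 11 (mPGK-E). Against a floor of 3 RNA reads over both replicates, the first was at least 2117-fold lower than its pool median and the last at least 1642-fold lower. PCR reads are not independent molecules, so such floors cover counting error only.

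The pools differed little in the median ratio of RNA to DNA share, each relative to its own listed barcodes. The median log2 ratio of RNA to DNA share ran from -1.52 in mPGK-D (95% bootstrap interval -1.61 to -1.40) to -1.15 in mPGK-F (-1.25 to -1.07), a range of 0.37 or 1.29-fold. Membership of a pool accounted for 0.269% of the variance between integrations, which was beyond chance in a permutation test of pool labels (two-sided, p = 1e-05, the smallest the 100000 resamples can give). Without mPGK-D the range was 0.21 (permutation p = 0.0094). Since each share is relative to the listed barcodes of its own pool, the medians do not compare absolute output between pools.

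Chromosome Y stood far below all other chromosomes. Its 9 integrations had a mean of -4.39 ± 3.14 (SD), and 55.6% of them lay more than 16-fold below the pool median, so that chromosome Y was 18.5-fold lower than the rest of the genome (difference -4.21 ± 1.05 SE). The size depended on low counts, with a difference of -3.35 at a 10 times larger pseudocount and -3.10 with integrations of fewer than 10 RNA reads left out. Among the autosomes, the highest was chromosome 11, known as gene-rich in the mouse, with a mean of 0.35 over 1063 integrations and a level 1.48-fold above the rest (difference 0.56 ± 0.08 SE, higher in 6 of 6 pools). Chromosomes 17, 7 and 4 followed with differences of 0.38, 0.30 and 0.30, each higher in 6 of 6 pools. Chromosome 5 had a difference of 0.20 that rested on mPGK-D, where it was 0.88. It was higher in 4 of 6 pools, with -0.15 in mPGK-A and -0.091 in mPGK-C, and the difference was 0.078 without mPGK-D. The lowest autosome was chromosome 14, 1.31-fold below the rest (difference -0.39 ± 0.09 SE, lower in 6 of 6 pools), followed by chromosomes 18, 12, 3, 13 and 1 with differences of -0.35, -0.28, -0.25, -0.23 and -0.20, lower in 6, 5, 5, 6 and 6 of 6 pools. By permutation within pools (two-sided, 100000 resamples, Benjamini-Hochberg over 21 chromosomes), 5 chromosomes were higher and 8 lower than the rest, counting X. The adjusted p was 7e-05 for chromosomes 11, 14 and Y, built on the smallest p the resamples can give, and 0.00037, 0.0005, 0.00094, 0.0016, 0.0044, 0.0044, 0.0092, 0.012 and 0.017 for chromosomes 4, 17, 7, 18, 3, 12, 1, 13 and 5. Chromosomes together accounted for 1.14% of the variance between integrations (permutation p = 1e-05, the smallest possible). Neighbouring integrations were alike, which such shuffling ignores, and when the values were instead rotated along the genome as a block (permutation by rotation), chromosome Y alone passed (adjusted p = 0.036, with 0.28 for chromosome 11 and 0.67 for chromosome 14), and the variance share did not pass (p = 0.29). At an unadjusted p of 0.05, rotation left 1 chromosome higher and 1 lower. The power of rotation for differences of chromosomes was not tested on simulated data, so these results do not show the chromosomes to be alike. Without pool mPGK-D, 5 chromosomes in place of 8 were lower and chromosomes 3, 5 and 12 did not pass (adjusted p = 0.07, 0.46 and 0.06), and without mPGK-E chromosome 1 did not (adjusted p = 0.11), nor at equal local density of integrations (adjusted p = 0.06).

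**Figure D1:**
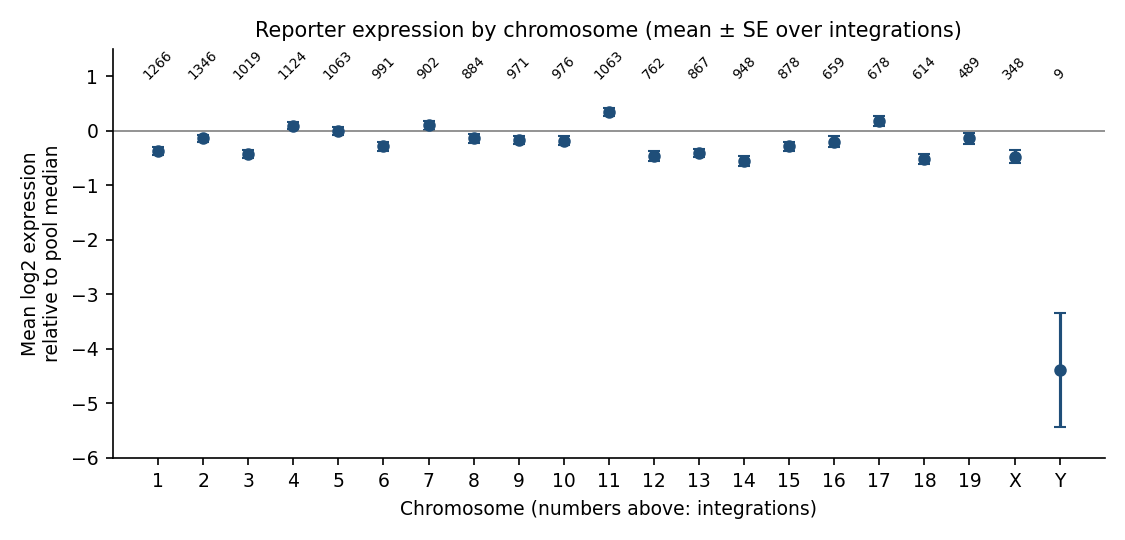
Mean log2 expression relative to the pool median (y axis) for each chromosome (x axis), with bars for the SE over its integrations and the number of integrations above each point. The autosomes and X lay between -0.55 (chromosome 14) and 0.35 (chromosome 11), and chromosome Y, with 9 integrations, at -4.39.

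Reporters on the X chromosome had a slightly lower mean than those on the autosomes, by a difference that did not hold up in every test and turned when integrations of equal local density were compared. The mean was -0.47 over 348 integrations on X and -0.18 over 17500 on the autosomes, a difference of -0.29 ± 0.13 (SE), or 1.23-fold lower (two-sided permutation test within pools, p = 0.024). X was below the autosomes in 5 of 6 pools, from -0.47 in mPGK-B to -0.18 in mPGK-A, and above them in mPGK-C (0.13, 49 integrations). Against all other integrations, the adjusted permutation p of X was 0.042, and above 0.05 without replicate 1 (0.057) or without mPGK-B, mPGK-D, mPGK-E or mPGK-F (0.13, 0.074, 0.12 and 0.093). The difference from the autosomes did not hold up in a permutation by rotation along the genome (p = 0.41), without mPGK-B, mPGK-E or mPGK-F (p = 0.08, 0.079 and 0.055), or with barcodes found in several pools used once (difference -0.22, p = 0.1, and adjusted p = 0.17 against all others). The power of rotation for a difference of X was not tested. Within classes of equal numbers of integrations within 100 kb, X lay 0.37 above the autosomes (permutation test within pools and classes, p = 0.0032), and with the numbers on X doubled, for a single copy against 2, it lay 0.057 above them (permutation p = 0.65). X also held the fewest integrations for its size, 2.18 per Mb of listed span.

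Reporters that had landed close together on a chromosome were expressed at similar levels, and the likeness faded with distance. Pairs of integrations 1 to 5 kb apart had a correlation of 0.439 ± 0.0273 (jackknife SE over chromosomes, 1348 pairs), and pairs within 1 kb a correlation of 0.421 ± 0.0299 (705 pairs). The correlation was 0.368 at 5 to 20 kb, 0.291 at 20 to 50 kb, 0.212 at 50 to 100 kb, 0.165 at 100 to 200 kb and 0.128 at 200 to 500 kb. It was 0.0847 at 500 to 1000 kb, 0.0510 at 1000 to 5000 kb and 0.0207 ± 0.00828 at 5000 to 20000 kb, over 1755752 pairs. Each of the 10 distance classes exceeded what permuting values within pool and chromosome gave (one-sided permutation test, adjusted p = 1e-05, the smallest possible). Such shuffling ignores the likeness of close neighbours, and the same integrations enter many pairs. The p-values of the distant classes may thus be too small, which was not tested, and the jackknife SE is the safer guide there. The correlations also include differences in level between chromosomes. Pairs whose members came from different pools gave nearly the same values, with 0.443 at 1 to 5 kb (1142 pairs). At 1 to 5 kb, 43.9% of the variance among the members of these pairs was thus shared by a neighbour. Error between replicates made up 5.15% of the variance over all integrations, which is another set than the members of such pairs.

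**Figure D2:**
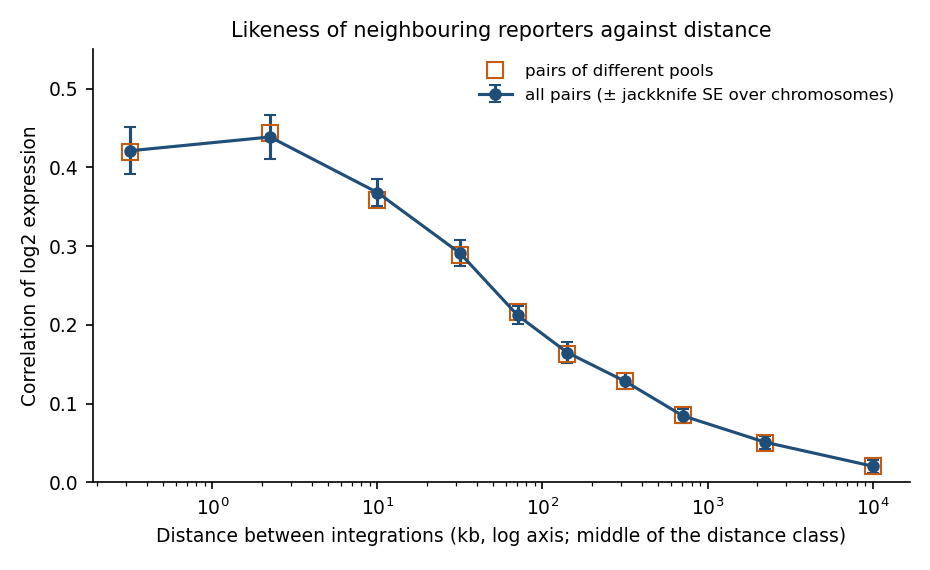
Correlation of log2 expression between integrations on the same chromosome (y axis) against their distance in kb (x axis, logarithmic, at the middle of each distance class). Filled points with bars show all pairs with the jackknife SE over chromosomes, open squares pairs of different pools; the correlation falls from 0.439 at 1 to 5 kb to 0.0207 at 5000 to 20000 kb.

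Windows of 2 Mb differed in mean expression when values were shuffled between integrations, while no single window stood out when values were rotated along the genome. Of the 1116 windows with at least 5 integrations, 75 were higher and 84 lower than the rest of the genome by shuffling (two-sided permutation test within pools, 100000 resamples, Benjamini-Hochberg at 0.05 over windows), and windows accounted for 16.6% of the variance between integrations, as a variance component corrected for the number of windows. Shuffling ignores the likeness of neighbours. By rotation, 0 windows were higher and 0 lower (two-sided permutation by rotation, smallest adjusted p = 0.31), with 19 higher and 54 lower at an unadjusted p of 0.05. Rotation also called 0 of 100 windows moved by 2 log2 units in simulated data, so these counts of 0 do not show windows to be alike. Chromosomes 4 and 11 each held 9 high windows, of 69 and 57 tested, and chromosome 17 held 7 of 40. They held 3, 2 and 0 low windows. Chromosomes 1 and 14 each held 8 low windows, of 82 and 55 tested, and 6 and 3 high windows. High windows held a median of 27 integrations and low windows a median of 9. The count of low windows was 52, 53, 47, 50 and 54 without mPGK-A, mPGK-B, mPGK-D, mPGK-E and mPGK-F, and it was 38 with 1 Mb windows and 34 with at least 10 integrations per window.

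Among the windows called by shuffling, the highest lay on chromosome 17 from 36000001 to 38000000, where 11 integrations from 6 pools lay 3.19 above the rest on the log2 scale, or 9.10-fold (permutation test, adjusted p = 0.004). On chromosome 4 from 140000001 to 142000000, which holds the pair of integrations at 140853193 and 140857158, 22 integrations averaged 2.79 ± 0.51, 7.89-fold above the rest and higher in 6 of 6 pools (permutation test, adjusted p = 0.0012, the smallest reached). Further windows were on chromosome 7, starting at 20000001, 2000001 and 26000001, with levels 5.98-fold, 5.98-fold and 5.48-fold above the rest. The others began at 8000001 on chromosome 19, 120000001 on chromosome 11, 46000001 on chromosome 17, 88000001 on chromosome 12 and 150000001 on chromosome 2, between 5.11-fold and 5.98-fold above the rest. The window at 46000001 on chromosome 17 held 40 integrations with a mean of 2.19 ± 0.27 (SE). By rotation, the adjusted p of these 10 windows ran from 0.5 to 0.76. By shuffling, 5 of them passed whichever pool was left out. The window at 36000001 on chromosome 17 did not pass without mPGK-C (adjusted p = 0.074), that at 20000001 on chromosome 7 without mPGK-A, mPGK-C or mPGK-D (0.072, 0.098 and 0.18), that at 26000001 without mPGK-A, mPGK-D, mPGK-E or mPGK-F (0.079, 0.18, 0.082 and 0.066), that at 8000001 on chromosome 19 without mPGK-B or mPGK-E (0.12 and 0.062), and that at 150000001 on chromosome 2 without mPGK-D (0.16), all by permutation. With the lowest 10% of DNA counts left out, those at 20000001 and 26000001 on chromosome 7 did not pass either (permutation test, adjusted p = 0.092 and 0.11).

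The lowest windows were mostly thinly filled, and their size depended on low counts. The 10 lay -4.83 to -3.88 from the rest on the log2 scale, and -3.84 to -2.61 with a 10 times larger pseudocount, with adjusted p up to 0.049 by shuffling. With integrations of fewer than 10 RNA reads left out, 5 of them could not be tested and the others lay -4.24 to -3.07 from the rest. By rotation, the adjusted p of the 10 ran from 0.31 to 0.62. On chromosome 14, 2 windows close to each other were low: from 94000001 to 96000000, 8 integrations averaged -5.01 ± 0.70 (SE) and lay -4.83 from the rest (-3.76 with the larger pseudocount, permutation test, adjusted p = 0.0014), and from 88000001 to 90000000, 10 integrations averaged -4.38 ± 0.77 and lay -4.19 from the rest (-3.38 with the larger pseudocount, permutation test, adjusted p = 0.0012). In both, every pool present lay below the genome mean. The window from 2000001 to 4000000 on chromosome Y had 5 integrations and a mean of -5.02 ± 1.85 (SE). On chromosome 16 from 60000001 to 62000000, 7 integrations, of which 2 had no RNA reads, lay -4.82 from the rest, or -3.84 with the larger pseudocount and -3.48 without those of fewer than 10 RNA reads. The others began at 72000001 and 124000001 on chromosome 3, 104000001 on chromosome 8, 18000001 on chromosome 1, 96000001 on chromosome 12 and 22000001 on chromosome 15, with 5 or 6 integrations each. DNA depth in the 10 windows had medians of 605 to 2668 reads, compared with 1670 over all integrations. By shuffling, both chromosome 14 windows passed whichever pool was left out, while the other 8 fell below 5 integrations without at least 1 pool and passed wherever they could still be tested.

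**Figure D3:**
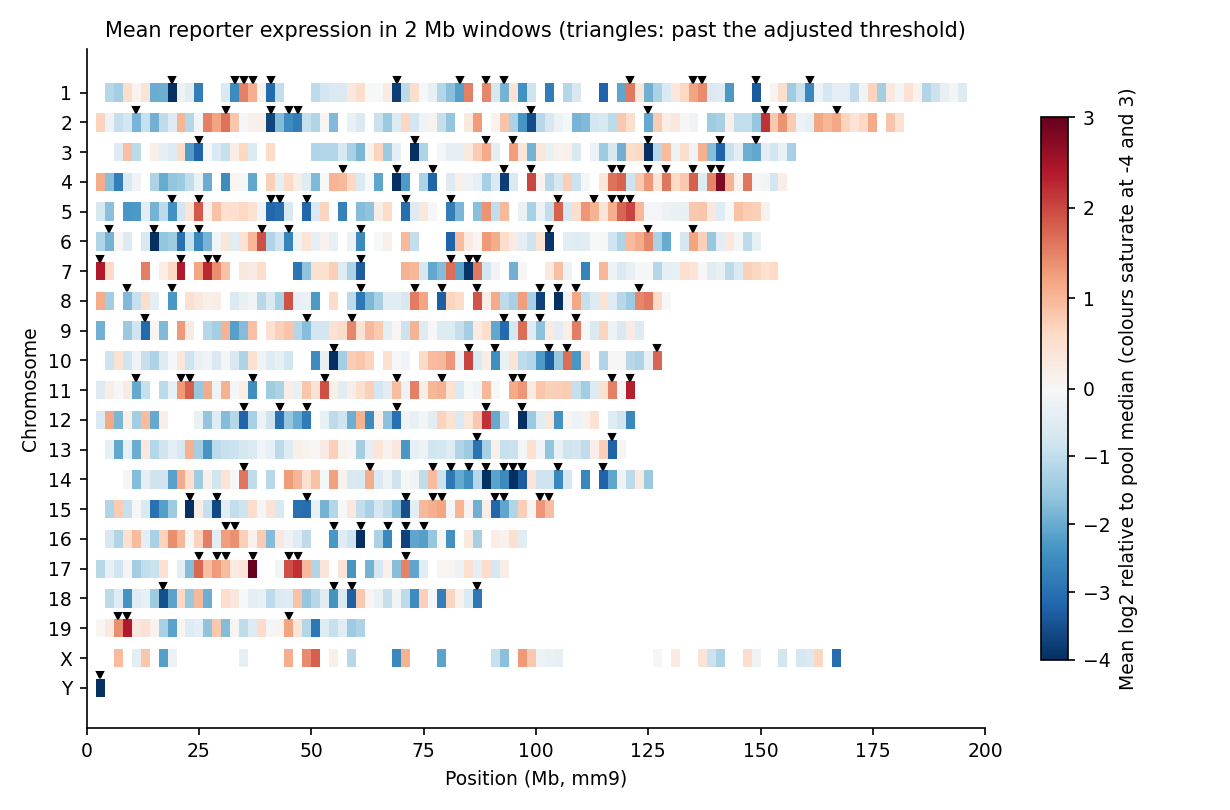
Map of 2 Mb windows with at least 5 integrations along each chromosome (y axis) by position in Mb on mm9 (x axis), coloured by mean log2 expression relative to the pool median, with blank stretches holding fewer integrations. Triangles mark the 75 high and 84 low windows past the adjusted threshold by shuffling; the 8 low windows on chromosome 14 lie in its right-hand part.

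Reporters in regions with many integrations were expressed more strongly than isolated reporters. The Spearman rho between expression and the number of other integrations within 100 kb was 0.343 across integrations, which are not independent replicates (two-sided permutation test within pools, p = 1e-05, the smallest possible, and adjusted p = 1.3e-05 over 4 relations). The 3248 integrations with no other within 100 kb had a mean of -1.37 ± 0.04 (SE), and the 156 with 10 or more had a mean of 2.00 ± 0.15. Among the isolated integrations, 12.4% lay more than 16-fold below the pool median, compared with 0.641% of those with 10 or more neighbours. The relation was present in each of the 6 pools, with rho from 0.321 in mPGK-F to 0.364 in mPGK-E, and rotating values along the genome gave p = 5.6e-05, the smallest possible. With neighbours counted within 10 kb, rho was 0.205.

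**Figure D4:**
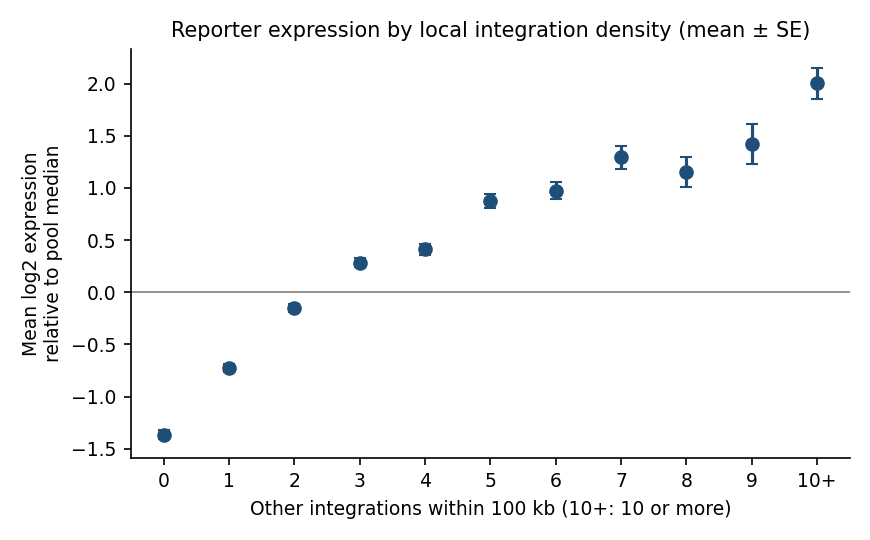
Mean log2 expression relative to the pool median (y axis) by the number of other integrations of any pool within 100 kb (x axis), with bars for the SE over integrations. Means rise from -1.37 with no other integration to 2.00 with 10 or more.

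The orientation of the reporter along the chromosome made no detectable difference to its level. The 8770 integrations on the plus strand averaged -0.20 and the 9087 on the minus strand -0.17, a difference of -0.023 (95% interval -0.094 to 0.048, two-sided permutation test within pools, p = 0.52), which turned to 0.011 without mPGK-D (permutation p = 0.78). The GC content of the barcode had a Spearman rho of -0.000799 with expression across integrations (two-sided permutation test, p = 0.9, adjusted p = 0.9 over the same 4 relations), and its sign turned without mPGK-D (0.00815) or mPGK-E (0.00228), with no call.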

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

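Whether pools differ in the level of a chromosome was tested for the 20 chromosomes with enough integrations in each pool, by permuting the residuals of pool and chromosome means, and this test was chosen after the data were seen. Chromosomes 2 and 5 passed (adjusted p = 0.033 for each). For chromosome 2 the difference from the rest ran from -0.43 in mPGK-B to 0.40 in mPGK-F on the log2 scale, over 183 to 249 integrations per pool. For chromosome 5 it was 0.88 in mPGK-D (158 integrations) and between -0.15 and 0.26 in the other pools. The permutation ignores the likeness of neighbouring integrations, so these p-values may be too small, which was not tested. A pool far from the others was looked for in 29 measures per pool, such as the median level, the error SD and the differences of chromosomes, and 0 of them passed Dixon's test over the 6 pools.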

How the results depend on the processing

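Tests by rotation, within classes of local density and with a minimum of 10 RNA reads, TMM scaling alone and single dropped count columns were chosen after seeing the data. Of the 203 alternative values of the main results, 177 kept their direction and side of the threshold or, for counts, stayed near the main count, among them all those of neighbour likeness (0.395 to 0.455 at 1 to 5 kb), local density, differences between pools and RNA against DNA counts, and those of high windows (51 to 92) but for rotation. TMM scaling alone gave 5863 higher and 6835 lower in place of 6585 and 6040, which turned the direction with more calls. With the lowest 10% of DNA counts left out, the median rho between replicates moved from 0.940 to 0.951 (the cause was not tested), and with the larger pseudocount the 5th to 95th percentile range moved from 7.84 to 7.10 log2 units, since low counts are raised. Under permutation by rotation along the genome, the variance share of chromosomes, 1.14%, had p = 0.29. Rotation left 0 chromosomes above and 1 below the rest in place of 5 and 8. It left 0 windows high and 0 low in place of 75 and 84 (19 and 54 unadjusted). Rotation keeps neighbours together, but it also called 0 of 100 moved windows in simulated data. Whether likeness of neighbours or low power lost these calls was not tested. Without single pools or replicates, 5 to 8 chromosomes were lower, with 5 when mPGK-D was left out. The X difference stayed between -0.36 and -0.26 without single pools or replicates, was -0.22 with shared barcodes used once and -0.29 under permutation by rotation (p = 0.41). Within classes of equal local density it turned to 0.37 (permutation p = 0.0032), and to 0.057 with the counts on X doubled (p = 0.65), with 0.37 and 0.059 against all other chromosomes; the cause was not tested. It lost its call without mPGK-B, mPGK-E or mPGK-F (-0.26, -0.26 and -0.28); the cause was not tested. Low windows numbered 47 to 80 in place of 84 without single pools or replicates, 34 with at least 10 integrations, where 829 in place of 1116 windows were tested, and 38 with 1 Mb windows, where 1556 were tested and the cause was not. The strand difference ran from -0.047 to 0.011 and turned sign without mPGK-D (permutation p = 0.78), and the rho of barcode GC ran from -0.00518 to 0.00815 without single pools, above 0 without mPGK-D (0.00815) and mPGK-E (0.00228), and was 0.00325 with the lowest 10% of DNA counts left out, with no call in any of these and the cause not tested. With the replicate number as a block, the RNA against DNA test gave 6532 higher and 5879 lower, with 12269 of 12625 calls shared; no other result was fitted with a block. The filter on low counts removed nothing, so that alternative is void, and leaving out a whole replicate leaves no residual degrees of freedom there, so that count columns were dropped singly (5207 to 6440 calls per direction). Depth limits low values most: the error SD was 2.24 log2 units at 10 to 29 RNA reads and 0.35 at 1000 or more.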

Other observations

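The tests of same-orientation neighbours at the same site and by distance, of X against 2 copies of each autosome, of the counts of 0 and of barcodes shared between pools were chosen after their result was seen. A hypothesis was that integrations without any RNA read sit at sites whose surroundings are low as well. Their neighbours within 20 kb that had reads averaged -0.76 (58 neighbour entries, SD 2.54), compared with 0.73 for neighbours of other integrations, lower than in all 100000 random draws of as many integrations from the same pools (one-sided permutation test, p = 1e-05, the smallest possible). This bears on low surroundings, not on shared silence: 0 pairs of integrations without RNA reads lay within 20 kb of each other, compared with 0.577 by chance (one-sided permutation test, p = 1), a number too small to show fewer or more. The random draws came from integrations of any level, and neighbours are alike in general. Low neighbours were thus not shown to be particular to integrations without RNA reads. Of the 184, 65 (35.3%) had no other integration within 100 kb, compared with 18% of the rest. They also had fewer DNA reads, with a median of 715 compared with 1685, so low depth may account for a part of them. They made up 0.579% of integrations in mPGK-F and 1.63% in mPGK-C.

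A hypothesis that local density carries the differences between chromosomes as a whole was tested. Most of their share of the variance stayed at equal density, though the set of differences changed. Within classes of equal numbers of integrations within 100 kb, chromosomes accounted for 1.25% of the variance left within the classes. Without classes they accounted for 1.14% of the whole variance, of which density itself accounted for 11%. The bases differ, so these shares do not show a rise. Chromosome 11 kept a difference of 0.50 and chromosome Y one of -3.72 (permutation test, adjusted p = 0.0001 and 0.00021), and chromosome 14 had -0.56. Chromosome 1 lost its call (-0.14, adjusted permutation p = 0.06), and chromosome 15, at -0.10 without classes, was at -0.33 (adjusted permutation p = 0.00014). At equal density chromosome X turned to 0.37 above the rest (permutation test within classes, adjusted p = 0.0072), and with its local counts doubled it was at 0.06. Shuffling within classes ignores the likeness of neighbours, as for the tests of chromosomes above. A further hypothesis, that chromosome ends differ, was not borne out by a detectable difference: integrations within 10 Mb of the first or last listed integration differed from the rest by -0.010 (3047 integrations, rotation within chromosomes as permutation test, p = 0.94), with -0.22 at the start (p = 0.2) and 0.15 at the end (p = 0.35).

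Neighbours within 1 kb were more alike when they pointed the same way. The correlation was 0.592 over 298 pairs of the same orientation and 0.320 over 407 pairs of opposite orientation, an excess of 0.272 (95% interval 0.160 to 0.386, permutation test, p = 4e-05). The permutation shuffled orientation classes over pairs as if these were independent, though an integration can enter several pairs. Its p-values here may thus be too small, which was not tested. The intervals come from resampling chromosomes. A clone read under several barcodes is argued against by pairs of different pools, with an excess of 0.270 (permutation p = 8e-05). Exchange of reads between near-identical barcodes of equal length is argued against by the 0 such pairs within 1 kb whose barcodes differ at 4 bases or fewer. Barcodes of unlike length were not compared base by base, so exchange between those was not tested. A wrong strand at pairs 1 bp apart is argued against by an excess of 0.251 without those pairs (permutation p = 0.00017). A candidate explanation, as a hypothesis, is that local transcription or regulation has a direction: the excess at 5 to 20 kb was smaller, 0.0899 (interval 0.0434 to 0.140, permutation p = 0.0053, adjusted p = 0.017 over 7 distance classes), though pairs 2 to 100 bp apart showed 0.0363 and pairs 2 to 5 kb apart 0.0482, with intervals that include 0, and no gene annotation was used here.

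The X chromosome held few integrations. It had 2.18 per Mb of listed span, compared with a median of 7.39 and a lowest value of 6.04 on the 19 autosomes. A single copy of X against 2 of each autosome would give a ratio of 0.5, and the ratio was 0.295 (95% interval 0.264 to 0.336), so this alone is argued against. Long stretches without listed integrations, the largest from 21733082 to 33291644, took 41.4 Mb of X, and without gaps of 2 Mb or more the ratio was 0.395 (0.350 to 0.441), wholly below 0.5, so a single copy and these stretches together are argued against as well. Lower mapping on X outside these stretches and fewer insertions stay open as untested. The labels do not give the sex of the line, though 9 integrations were listed on chromosome Y.

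RNA counts of 0 were more frequent than sampling of reads gives. At 265 integrations with 10 RNA reads or more, all reads were in a single replicate, with up to 94 reads against 0, while an even random split of independent reads gives 0.134 such integrations. A fixed minimum below which all counts were written as 0 is argued against by 148 counts of 1 to 3 reads. These were fewer than the 378 counts of 4 to 6 reads, and a minimum applied to only a part of the counts was not tested. That few RNA molecules were copied into many reads may account for this, with an error SD of 2.24 log2 units at 10 to 29 RNA reads, but a loss of expression in a single culture would look alike and cannot be told apart from it without molecular identifiers. Over both replicates, 184 integrations had 0 reads, compared with 13 with 1 read and 14 with 2.

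A hypothesis that the barcode sequence sets expression was tested on barcodes found in several pools. Of 17339 barcodes, 506 were listed in more than 1 pool, giving 531 pairs at different sites, 0 of them within 10 kb. Their expression had a correlation of 0.0596 (95% interval -0.0501 to 0.159, permutation test, p = 0.17), below the 0.2 set as a bound. Sharing of this size by chance corresponds to a library of 249835 equally frequent barcodes. No integrations shared position and strand, while 80 pairs lay 1 bp apart on opposite strands with the minus strand first in each, 15 of them in the same pool, and these pairs had a correlation of 0.211. From 2 to 300 bp, 114 of 239 pairs (47.7%, exact 95% interval 41.2% to 54.2%) had the same orientation.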
